A study of Macaca mulatta with 2 samples.

How the data were processed

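Single-cell RNA sequencing was done on trabecular meshwork tissue of rhesus macaques, with 1 library labelled glaucoma and 1 labelled normal. The labels do not state how many animals or eyes gave each library, nor their age, sex or eye pressure. Both libraries had the same protocol per the labels: digestion in 5 mg collagenase at 37 °C for 20 minutes, a 70 µm filter, a target of 10000 captured cells, 12 cycles of cDNA amplification and a droplet-based 3-prime kit of version 3.

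The deposited values were counts: unique molecular identifiers (UMIs) per gene and cell barcode, as whole numbers without normalization, 1 matrix per library. The authors made these counts with Cell Ranger, but the sources differ on its version. The processing notes of the submitters list Cell Ranger 4.0 and Seurat 3.0, while the header of both matrices names Cell Ranger 6.0.0. No barcode held fewer than 500 UMIs in either matrix, and the sources used here do not say which rule chose the barcodes. The genome build and annotation were not given in the sources used here, and genes were identified by Ensembl macaque identifiers. The deposited matrices hold the cells of 1 library each, and no cell annotation came with them.

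Both libraries listed the same 24037 features, of which 15580 had a symbol in the files. A further 879 took a symbol from the reference table of gene names, and 103 did not because that symbol was already in use. The remaining 7475 had no symbol and could not be matched to any list. EDN1 and XIST were among the genes with no named feature and were not analysed here. The features included 12 mitochondrial, 79 ribosomal protein and 2 haemoglobin genes.

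Cells were kept with at least 500 genes detected and under 20% mitochondrial UMIs, after removal of the doublets that Scrublet called in each library at an expected rate of 0.8% per 1000 cells. Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1 and igraph 0.11.9 was used, with seed 1. Both libraries were clustered together without integration: scaling to 10000 UMIs per cell, log transformation, 2000 variable genes chosen with the library as batch, 30 principal components, 15 nearest neighbours weighted by the neighbours they shared, and Leiden clustering at resolution 1, which gave 25 clusters.

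Clusters were named from 19 marker sets fixed before the data were examined, and each class is called "like" its type for that reason. The cycling set was among them, but the rule could not name a cluster from it. The rule for naming was settled only after the clusters had been seen, and another order of its steps was tried and dropped. A marker counted when its CPM (UMIs per 1e+06 UMIs, with 10 added) was at least 2-fold above the median cluster and at least 10% of the cluster's cells held a UMI. A cluster took the class with most markers, if there were at least 3. It took the lymphatic-type class over the vascular class when at least 3 lymphatic-type markers counted, since the vascular set holds genes of all endothelium. The 10 leading genes of a cluster were its highest named genes with a UMI in at least 25% of cells. A cluster was left unnamed when another class had more of these 10 genes, or as many with more than 1. It was also left unnamed when its median depth was below that of the libraries divided by 3 and no leading gene was a marker.

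Each group had 1 library, so no test between the groups was possible and no p-value is given. Cells of 1 library are not replicates. Shares of kept cells have exact (Clopper-Pearson) 95% binomial intervals. Expression within a class was the sum of UMIs per gene over its cells, as CPM of the class total with exact Poisson intervals, and was compared as the log2 ratio of the glaucoma library over the normal library. The 95% interval of that ratio is exact (conditional binomial, Clopper-Pearson). Intervals in brackets and the upper limits at a count of 0 (3 counts) cover counting error only, not the spread between animals, dissections or batches. Classes with at least 50 kept cells in each library were compared, which left 9, and genes needed at least 100 UMIs over both libraries in the class. A gene was called higher or lower when its ratio was at least 2-fold and its interval excluded 1; other genes are described as between.

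Before the data were examined, 27 gene lists were fixed, and 26 of them are reported here. These are contractile filaments, calcium handling, nitric oxide and cyclic nucleotide relaxation, endothelin and contractile receptors, fibrillar and basement membrane matrix, matrix turnover, TGF-beta and BMP signalling, integrins and focal adhesion, Wnt signalling, inherited glaucoma and outflow loci, juxtacanalicular markers, beam cell markers, immediate early and dissociation stress genes, heat shock, endoplasmic reticulum stress, oxidative stress defence, inflammation, interferon response, antigen presentation, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, aquaporins and ion transport, senescence, sex-linked genes, the mitochondrial genome, and damaged-cell and nuclear RNA. A list with at least 5 measured members in a class was summarised by the median log2 ratio of its members. The interval of the median came from 1000 Poisson draws of the counts. Its percentile was taken among 10000 random lists of the same size, matched over 20 bins of expression, and describes these 2 libraries only. Both the interval and the percentile treat the members of a list as independent. Genes regulated together can therefore reach extreme percentiles more often than these random lists allow for.

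Genes to be named were chosen by a rule fixed in advance. In trabecular meshwork-like cells these were the 12 highest and the 12 lowest ratios among genes with a symbol, a UMI in at least 5% of the class cells of 1 library, an at least 2-fold ratio whose interval excluded 1, and no place among the marker sets or the mitochondrial, ribosomal protein, haemoglobin and sex-linked genes. In every other class compared they were the 4 highest and the 4 lowest. Besides, they were the 2 highest and 2 lowest measured members of each list, up to 4 each way for the lists on contraction, and always, among others, MYOC, ACTA2, TAGLN, MYL9, MYLK, NOS3, EDN1, FN1, SPARC, TGFB2 and CAV1. The list left out, its members and 2 further genes that this rule chose are not reported, and the counts of named genes and of alternatives leave them out.

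The calculations were tested on simulated counts with 200 genes set apart by a log2 ratio of 1.5 or 2.5. These counts were Poisson draws from a pooled profile of the class, as the intervals assume, with no spread between cells. They check the calculation only, not how well the intervals suit these data. The intervals held the true ratio for 95.4% of 8307 genes at the depth of trabecular meshwork-like cells, 95.4% of 6476 at that of muscle-like cells and 96.6% of 820 at that of T or NK cell-like cells. Of the genes with the smaller simulated ratio, 99%, 100% and 100% were called in the right direction. A list of 20 genes with no simulated ratio reached the percentile 54.9, 99.4 and 89.8, with a median of 0.06 in the second, so a high percentile can stand beside a very small median.

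The alternatives fixed in advance were every deposited barcode kept, a stricter filter (at least 1000 genes and under 10% mitochondrial UMIs), doublets kept, each library clustered separately, and integration with Seurat 5.3.0 anchors. For genes and lists they were also TMM scaling (edgeR 4.0.16 in R 4.3.3), the same weight for every cell, cells thinned to 1000 UMIs, CPM without mitochondrial, ribosomal protein and haemoglobin genes, and no UMI minimum. Alternatives chosen after the data had been seen were naming by the number of markers alone, single trabecular meshwork-like and muscle-like clusters, the same weight in both libraries for each trabecular meshwork-like cluster, the muscle-like class without cluster 17, and each sum without its highest barcode. Figures were drawn with matplotlib 3.10.9.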

Results

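The data were 2 single-cell RNA libraries of macaque trabecular meshwork, the sieve of cells and matrix through which aqueous humour leaves the eye, 1 library per group. The glaucoma library held 10624 barcodes with 38765808 UMIs, a median of 2746 UMIs and 1225 genes per barcode. The normal library held 7028 barcodes with 25042621 UMIs, a median of 2317 UMIs and 1107 genes. In the glaucoma library 906 barcodes had under 500 genes and 1366 had 20% or more mitochondrial UMIs, against 1104 and 911 in the normal library. Doublet calls took a further 296 cells (3.43%) and 45 cells (0.829%), below the 6.91% and 4.34% that loading predicts. Kept were 8337 glaucoma cells with 30011671 UMIs (78.5% of barcodes) and 5385 normal cells with 21696437 UMIs (76.6%). Their medians were 2751 and 2702 UMIs, 1243 and 1291 genes, and 3.82% and 3.17% mitochondrial UMIs. HBB, a haemoglobin gene of red blood cells, gave 38881 UMIs in the glaucoma library and 141196 in the normal library before any filter. There were no replicates, so the diagnosis cannot be told apart from the animal, the dissection or the day of preparation.

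The first comparison asked which cell types made up the tissue in each library, a question the series names. Trabecular meshwork-like cells, the class with the outflow genes MYOC and CHI3L1, were 22.1% [21.2, 22.98] of kept glaucoma cells and 15.8% [14.8, 16.8] of normal cells, a log2 ratio of 0.48 [0.36, 0.60]. Stromal fibroblast-like cells were lower in the glaucoma library, 15.5% [14.7, 16.3] against 29.5% [28.3, 30.8] (log2 ratio -0.93 [-1.04, -0.83]). Muscle-like cells, with DES and MYH11, were lower as well, at 8.37% [7.79, 8.99] against 19.6% [18.6, 20.7] (-1.23 [-1.37, -1.09]). Over every deposited barcode their log2 ratio was -0.53. Lymphatic-type endothelium-like cells were 6.60% (550 cells) against 0.613% (33 cells), a log2 ratio of 3.43 [2.92, 3.98]. Their cluster was named from 4 markers of the lymphatic-type set, with CCL21 and MMRN1 among its leading genes. That set includes PROX1, which lymphatic vessels and Schlemm's canal share. Macrophage-like cells were also a larger share of the glaucoma library, at 7.60% against 2.82% (1.43 [1.17, 1.69]). So were T or NK cell-like cells, at 3.96% against 2.14% (0.89 [0.58, 1.21]).

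Vascular endothelium-like cells made up 7.70% of glaucoma and 5.74% of normal cells (0.42 [0.23, 0.62]). Melanocyte-like cells, with the pigment cell markers PMEL and TYR, were 1.08% (90 cells) against 0.297% (16 cells), a log2 ratio of 1.86 [1.08, 2.73]. Myelinating Schwann cell-like cells were 2.43% against 4.53% (-0.90 [-1.17, -0.62]). For pericyte-like cells (6.26% and 6.15%) and non-myelinating Schwann cell-like cells (10.5% and 10.7%), the intervals of the log2 ratio, [-0.17, 0.23] and [-0.18, 0.13], included 0. B or plasma cell-like cells numbered 13 and 8, with a log2 ratio of 0.07 [-1.31, 1.55]. Unnamed clusters 10, 13 and 21 held 7.80% of glaucoma and 1.93% of normal cells. With the cells kept here, no cluster was named mast cell, neutrophil, surface epithelium, ciliary epithelium, corneal endothelium or erythroid, so those classes have no share. Unnamed cluster 10 had 6 macrophage and 3 neutrophil markers, with S100A8 and S100A9 among its leading genes. Over every deposited barcode, 37 glaucoma and 74 normal cells were erythroid-like. Surface epithelium-like cells numbered 0 and 13 with the libraries clustered separately, and 14 and 22 after integration.

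Several shares depended on the processing. The trabecular meshwork-like log2 ratio was -0.11 with doublets kept (1308 glaucoma and 108 normal cells in unnamed clusters), 0.84 with the libraries clustered separately and 0.16 after integration. Under the stricter filter, which removes the shallow cells of some classes, it was -1.49 for pericyte-like and -1.47 for non-myelinating Schwann cell-like cells, whose median depths were 1434.5 and 965 UMIs in the glaucoma library and 2288 and 1313 in the normal library. The muscle-like and stromal fibroblast-like ratios were both -0.53 over every deposited barcode. Among those barcodes muscle-like cells numbered 1975 in the glaucoma library and 1890 in the normal library, against 698 and 1056 kept. Their median mitochondrial share was 23.6% in the glaucoma library and 14.9% in the normal library. The limit of 20% thus took a larger part of this class from the glaucoma library. The lymphatic-type ratio stayed between 3.35 and 3.53, and the macrophage-like ratio between 1.27 and 1.47, under the 5 alternatives fixed in advance.

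**Figure D1:**
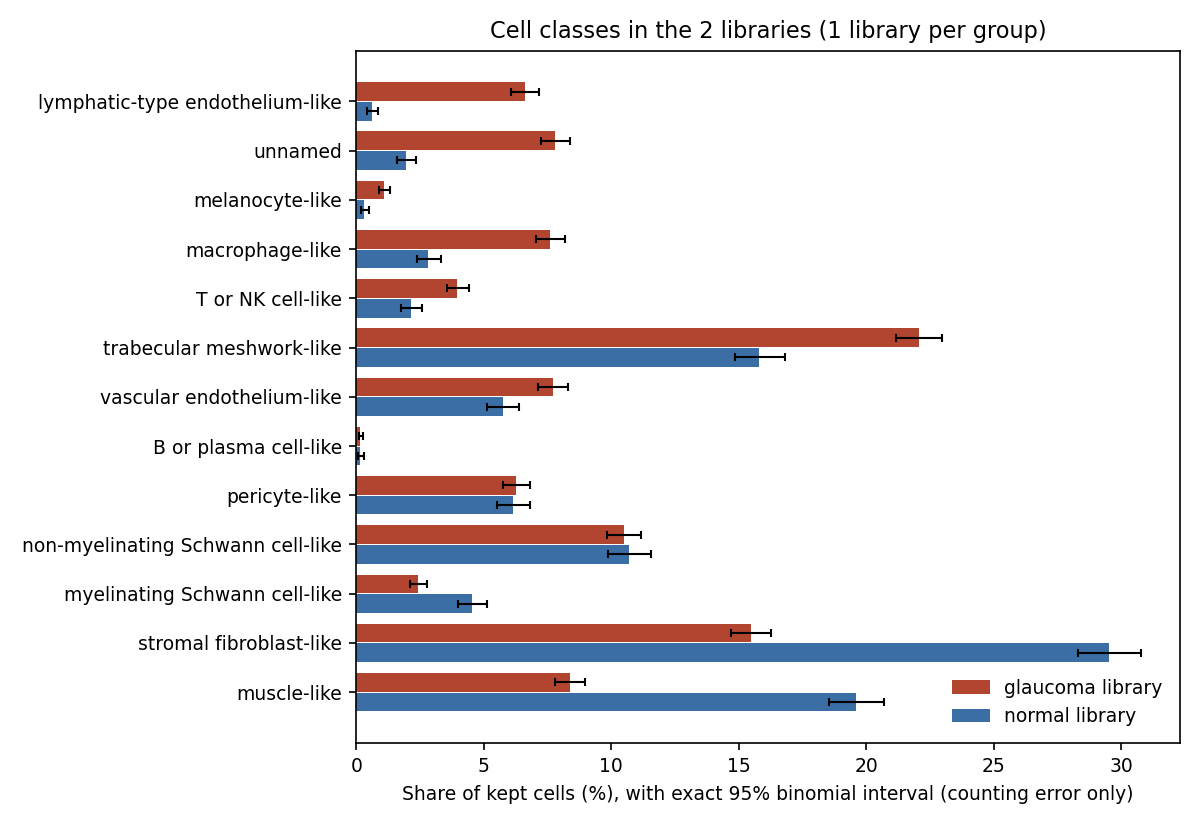
Share of kept cells in each class (%, horizontal axis) in the glaucoma library (8337 cells) and the normal library (5385 cells), with exact 95% binomial intervals of counting error. Lymphatic-type endothelium-like cells were 6.60% against 0.613%, while stromal fibroblast-like cells were 15.5% against 29.5%.

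The main comparison asked how genes of contraction differed within trabecular meshwork-like cells, since the series is about relaxation and contraction of this tissue. Contractile filament genes stood higher in the glaucoma library: 5 of 25 measured members were called higher, 0 lower and 20 between, with a median log2 ratio of 0.39 [0.36, 0.43] at percentile 99.9 of random lists. TAGLN (ENSMMUG00000002058), an actin-binding protein of contractile cells, was at 3854 CPM in the glaucoma library and 1712 CPM in the normal library (1.17 [1.14, 1.20]). ACTA2 (ENSMMUG00000009341), smooth muscle alpha-actin, was at 507 and 192 CPM (1.40 [1.31, 1.49]). CNN1, calponin, was at 122 and 42.4 CPM (1.52 [1.33, 1.72]), and the intermediate filament gene DES at 57.8 and 21.8 CPM (1.41 [1.14, 1.68]). ACTB, cytoplasmic beta-actin, stood at 1.03. Among members between the limits, MYL9, a myosin light chain, had a ratio of 0.47 [0.41, 0.53]. The lowest were TPM3 (-0.79), CNN2 (-0.43), MYLK, the myosin light chain kinase (-0.39 [-0.49, -0.28]), and VCL (-0.19).

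The libraries drew their trabecular meshwork-like cells from different clusters. Cluster 2 held 49.3% of the class in the glaucoma library and 16.0% in the normal library, cluster 3 held 32.6% and 1.998%, cluster 6 held 2.12% and 14.2%, cluster 20 held 8.75% and 60.2%, and cluster 23 held 7.23% and 7.64%. Clusters 2, 3, 6 and 20 lie mostly in 1 library each and can be marks of that library rather than cell types. The median depth of the class was 5494 UMIs in the glaucoma library and 7350 in the normal library, with 3.63% and 1.60% mitochondrial UMIs. TAGLN and ACTA2 were higher in the glaucoma library in 5 of 5 clusters, with an interval above 0 in 4 of 5, and CNN1 was higher in 4 of 5, with an interval above 0 in 2. With the same weight for each cluster in both libraries, the list's median was 0.22 [0.14, 0.29], ACTA2 stood at 1.18, TAGLN at 0.88 and CNN1 at 0.60. Such weighted values rest in part on few cells, as cluster 3 held 17 normal cells and cluster 6 held 39 glaucoma cells. The counting interval does not cover the spread between those cells. Of the 86 named genes of this class that were called higher or lower, 49 kept an at least 2-fold ratio in the same direction with these weights. The median was 0.16 with doublets kept and 0.15 after integration, and 0.06 [-0.14, 0.14] in cluster 23 alone.

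**Figure D2:**
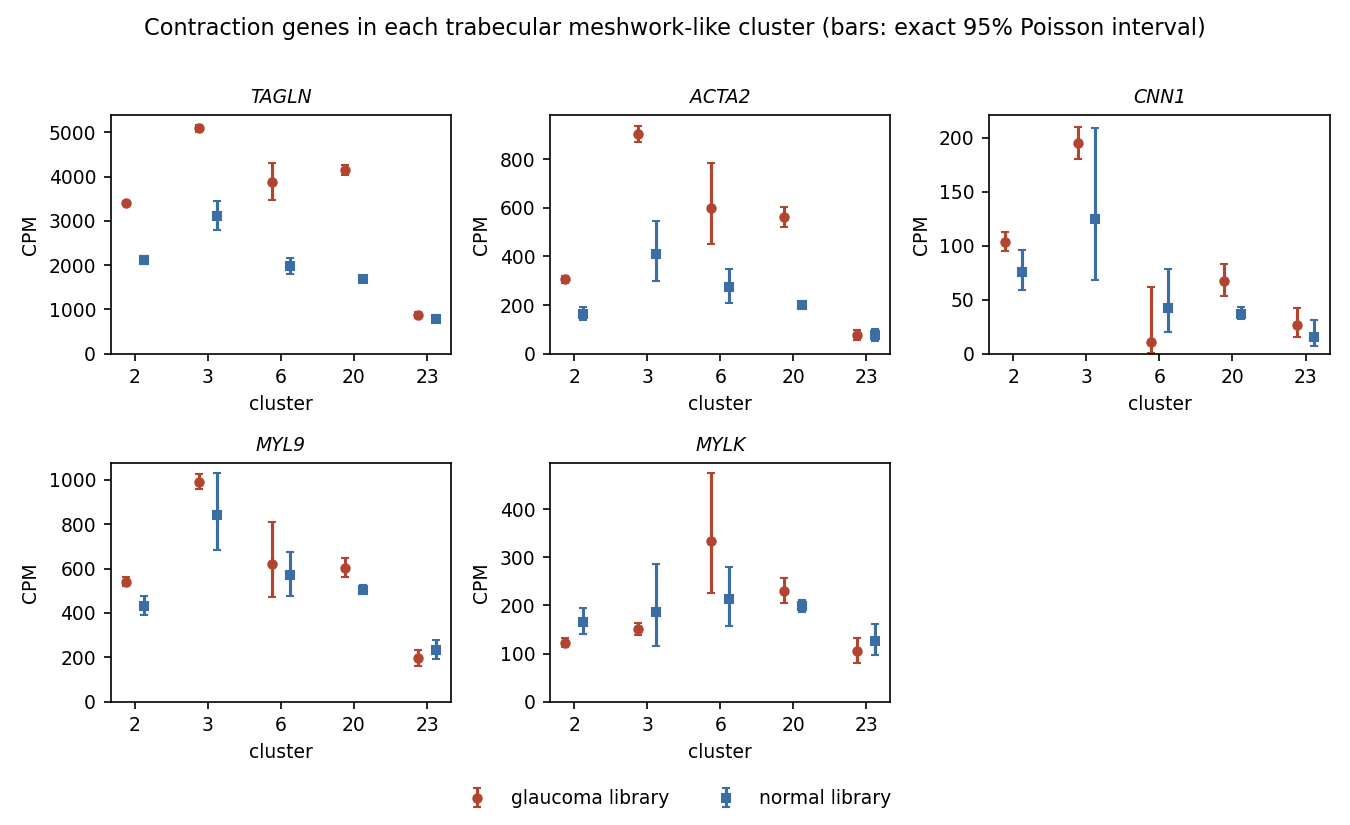
CPM of 5 contraction genes (vertical axes) in each of the 5 trabecular meshwork-like clusters (horizontal axes) of the glaucoma and normal libraries, with exact 95% Poisson intervals. TAGLN and ACTA2 were higher in the glaucoma library in 5 of 5 clusters, and CNN1 was higher in 4 of 5.

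The same filament list was also higher in immune and Schwann cell-like classes, which are not contractile. Its median was 1.37 [1.16, 1.63] in T or NK cell-like cells, where TAGLN was at 725 and 63.7 CPM, 0.54 [0.30, 0.66] in macrophage-like cells (but -0.26 with the libraries clustered separately), 0.38 [0.22, 0.54] in non-myelinating and 0.37 [0.26, 0.49] in myelinating Schwann cell-like cells. It was 0.19 in muscle-like cells, 0.10 in stromal fibroblast-like cells, -0.02 in pericyte-like cells and -0.06 in vascular endothelium-like cells. Some values in T or NK cell-like cells leaned on single glaucoma barcodes. The top barcode held 17.9% of the TAGLN UMIs, 19.7% for ACTA2, 21.1% for TPM2 and 23.7% for CALD1. These barcodes held 4016 to 6151 UMIs, against a class median of 1353.5 in that library. Without them the log2 ratios were 3.24 for TAGLN, 1.86 for ACTA2, 2.44 for TPM2 and 2.51 for CALD1. In TAGLN, ACTA2 and CNN1 the excess per trabecular meshwork-like cell of the glaucoma library was 11.9, 2.97 and 3.71 times the highest level per cell in the immune and Schwann cell-like classes. In DES it was 0.651 times that level, and in ACTB, which macrophages hold in plenty, 0.199 times.

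Upstream of the filaments, the signals that start or end contraction did not share the higher level of trabecular meshwork-like cells in the glaucoma library. In calcium handling 0 of 16 members were called higher, 1 lower and 15 between, with a median of -0.31 [-0.36, -0.12] at percentile 4.47, and of -0.09 with no UMI minimum. RYR2, a calcium release channel, was called lower (-1.76 [-2.23, -1.31]), while STIM1 (-0.57), ITPR2 (-0.51), ATP2B4 (-0.47), CALM2 (0.06), CAMK2G (0.23), ORAI1 (0.44) and PLN (0.72) were between. For PLN 1 barcode held 43.5% of the UMIs in the normal library, and the ratio was 1.54 without it. RYR2 stood at -1.16 with the same cluster weights. In nitric oxide and cyclic nucleotide relaxation 2 of 16 were higher, 2 lower and 12 between, with a median of -0.03 [-0.16, 0.10]. The prostaglandin E receptor gene PTGER4 was lower (-2.04 [-2.37, -1.72]), as was the phosphodiesterase PDE4D (-1.09), and KCNMB4 was higher (1.12), with PDE5A (-0.83), ADCY5 (-0.79), GUCY1B1 (0.50) and VASP (0.62) between. With the same cluster weights that list's median was -0.42 [-0.60, -0.23]. In endothelin and contractile receptors 2 of 12 were higher, 2 lower and 8 between, with a median of -0.18 [-0.24, -0.03], which was 0.12 in cells thinned to 1000 UMIs. PLCB1 (-1.65, but -0.38 with the same cluster weights) and S1PR3 (-1.10) were lower, and CHRM3 (-0.42), ECE1 (-0.27), EDN3 (0.42) and EDNRB (0.45) were between, the last 2 at -0.44 and -0.18 with the same cluster weights. Called higher were EDNRA, the endothelin A receptor (1.40 [1.15, 1.65]), PLCB4 (1.03) and, of the relaxation list, PTGER2 (1.59), but with the same cluster weights they stood at -0.49, -0.40 and -0.13. NOS3, endothelial nitric oxide synthase, had too few UMIs in trabecular meshwork-like cells and was at 355 and 436 CPM in vascular endothelium-like cells (-0.30 [-0.50, -0.09]).

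Matrix genes of trabecular meshwork-like cells were higher as a list: 7 of 29 measured members of fibrillar and basement membrane matrix were called higher, 1 lower and 21 between, with a median of 0.35 [0.22, 0.42] at percentile 99.4. The highest were POSTN (2.16, but 0.50 at the same cluster weights) and COL18A1 (1.97), the lowest LUM (-1.02, called lower) and COL12A1 (-0.76). At those weights COL18A1 stood at 1.3, LUM at -0.87 and COL12A1 at -0.07. FN1, fibronectin, was at 99.03 and 77.5 CPM (0.35 [0.20, 0.51]) and SPARC, a matricellular protein, at 871 and 1096 CPM (-0.33 [-0.37, -0.29]). With the same cluster weights the median of the list was 0.06 [-0.05, 0.19], and FN1 stood at -0.31. In matrix turnover 3 of 17 were higher, 3 lower and 11 between, with a median of -0.08 [-0.27, 0.04]. TIMP3, an inhibitor of matrix metalloproteinases, was at 1234 and 3845 CPM (-1.64 [-1.67, -1.61]) and the protease gene ADAMTS1 at -2.08, while the protease inhibitor gene SERPINE2 (1.96) and the plasminogen activator gene PLAT (1.28) were higher. With the same cluster weights TIMP3 stood at -0.53 and SERPINE2 at 0.29.

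TGF-beta and BMP signalling, a pathway long tied to matrix build-up in this tissue, was lower as a list, with 1 of 26 members called higher, 5 lower and 20 between and a median of -0.50 [-0.55, -0.42], below all 10000 random lists, which was -0.37 with the same cluster weights. TGFB2 was at 154 and 377 CPM (-1.29 [-1.38, -1.20]; -0.53 with the same cluster weights) and its co-receptor TGFBR3 at 82.7 and 234 CPM. LTBP4 was higher (1.45) and TGFB1 was between (0.97), but they stood at 0.95 and 1.22 with the same cluster weights. The Wnt signalling list was lower too, with 1 of 15 higher, 3 lower and 11 between. Its median was -0.51 [-0.65, -0.27] at percentile 0.25, and -0.24 [-0.49, -0.17] with the same cluster weights. Both lists hold antagonists beside activators, so their medians give no direction of signalling. The Wnt antagonist gene SFRP1 was at 197 and 583 CPM (-1.56 [-1.64, -1.49]) and CTNNB1 at -1.21, with LRP5 between (0.77). RSPO3 was higher (1.66), but at 0.13 with the same cluster weights. The median of integrins and focal adhesion was 0.07 [-0.19, 0.12], with 1 of 17 higher, 1 lower and 15 between. In that list CAVIN2 was at 3.14 and ITGA2 at -1.59, but at 0.27 and 0.16 with the same cluster weights. ZYX was at 0.75, PTK2 at -0.57, and CAV1 was at 34.6 and 28.5 CPM (0.28 [0.02, 0.54]; -0.66 with the same cluster weights).

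Of the inherited glaucoma and outflow loci, 0 of 18 measured genes were called higher, 4 lower and 14 between (median -0.19 [-0.30, -0.14]). MYOC (ENSMMUG00000013649), the gene of myocilin, was at 24417 and 31055 CPM (-0.35 [-0.36, -0.34]) and higher in 3 of 5 clusters. ANGPT1, a ligand of the TEK receptor, was at 218 and 493 CPM (-1.18 [-1.25, -1.10]), but stood at -0.31 with the same cluster weights, and LTBP2 was at -1.12. FOXC1, a transcription factor of the anterior segment, was at 219 and 123 CPM (0.84 [0.72, 0.95]) and higher in 5 of 5 clusters, and OPTN was at 0.45. Beam cell markers had a median of -0.06 [-0.23, 0.12] over 7 genes, with 1 higher, 0 lower and 6 between. Among them PPP1R1B (3.56) stood at -0.06 with the same cluster weights, TMEFF2 was at 0.83, RARRES1 at -0.41 (0.36 with the same cluster weights) and BMP5 at -0.93. Of the juxtacanalicular markers 4 were measured, too few for a median: CHAD was lower (-2.64, but -0.43 with the same cluster weights), while ANGPTL7 (-0.71), FMOD (-0.50) and CHI3L1 (0.01) were between. CHI3L1 was nonetheless higher in 5 of 5 clusters and stood at 1.03 with the same cluster weights.

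**Figure D3:**
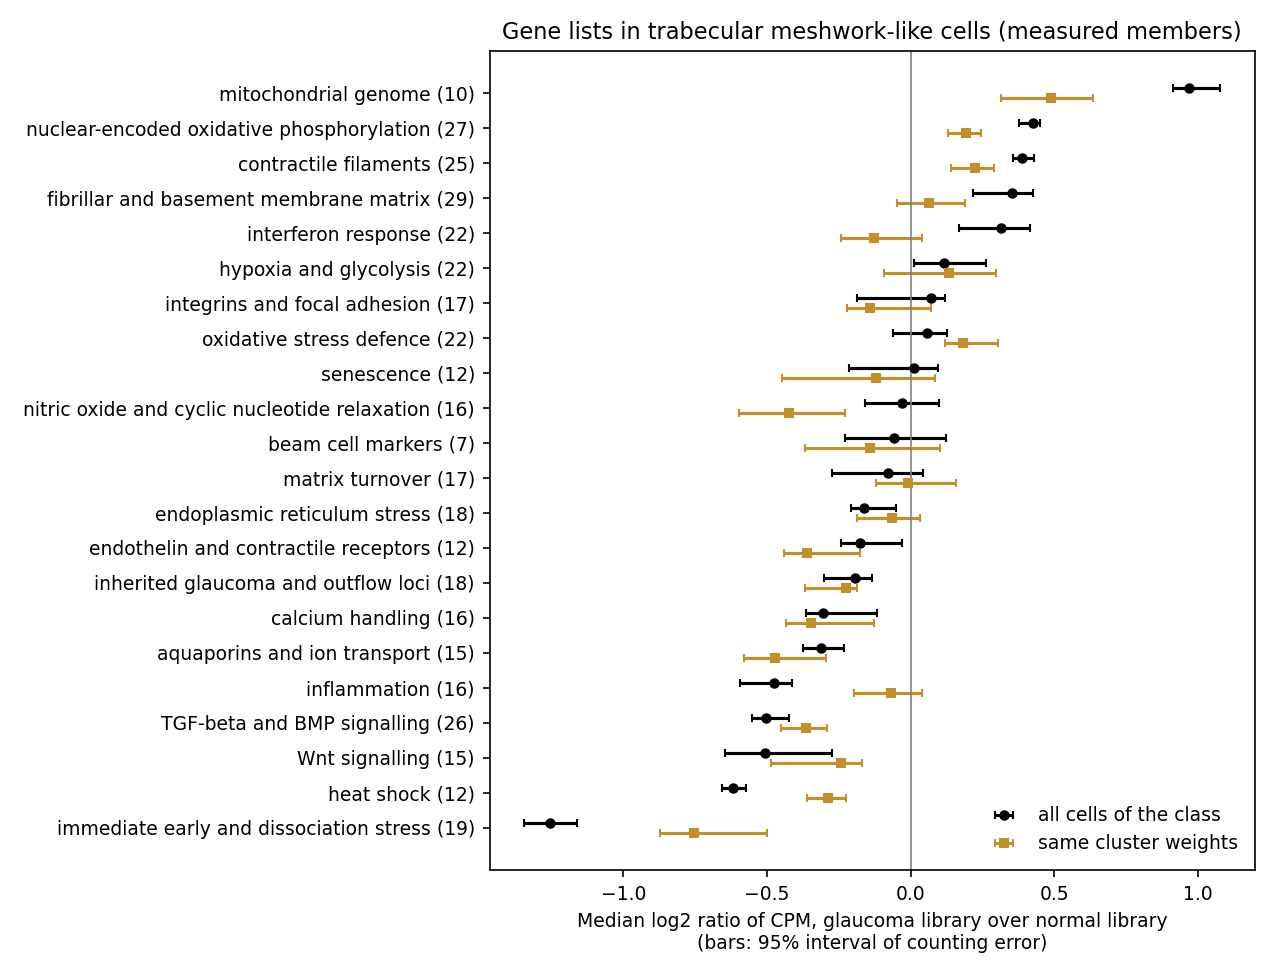
Median log2 ratio (glaucoma over normal library, horizontal axis) of the gene lists with at least 5 measured members in trabecular meshwork-like cells (number measured in brackets), over all cells of the class and with the same cluster weights; bars are 95% intervals of counting error. Contractile filaments stood at 0.39 and 0.22, immediate early genes at -1.26 and -0.75.

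Genes that respond within minutes to stress were lower in trabecular meshwork-like cells of the glaucoma library. Of the immediate early and dissociation stress genes 1 of 19 was called higher, 10 lower and 8 between, with a median of -1.26 [-1.34, -1.16], below all 10000 random lists. EGR1 was at 571 and 2260 CPM (-1.98 [-2.03, -1.94]), NR4A3 was the lowest (-3.02), JUNB was between (-0.07) and JUND higher (1.17). This list was below 0 in 9 of 9 classes. Heat shock genes followed, with 1 of 12 higher, 4 lower and 7 between and a median of -0.62 [-0.66, -0.57], which was -0.29 [-0.36, -0.22] with the same cluster weights. The chaperone gene DNAJB1 was at 341 and 1608 CPM (-2.24 [-2.29, -2.18]), BAG3 at -2.48 and HSPE1 at 0.38, with DNAJB1 at -1.48 and BAG3 at -1.30 under the same cluster weights, while the small heat shock protein gene CRYAB was higher, at 4734 and 1929 CPM (1.29 [1.27, 1.32]), but at 0.70 with the same cluster weights and -0.14 in cluster 23 alone. The inflammation list was lower, with 2 of 16 higher, 5 lower and 9 between and a median of -0.48 [-0.59, -0.41]. The cytokine genes CXCL2 (-2.84) and IL6 (-2.58) were lower, and IL11 (2.89) and VCAM1 (1.53) higher. With the same cluster weights CXCL2 stood at -2.07, IL6 at -2.04, IL11 at 2.19 and VCAM1 at 1.45. The median was -0.07 [-0.20, 0.04] with the same cluster weights, but -0.46 [-0.66, -0.41], -0.41 [-0.72, -0.36] and -0.41 [-0.74, -0.02] in clusters 2, 20 and 23 alone, over 13, 11 and 5 members.

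As lists, genes of respiration were higher in trabecular meshwork-like cells of the glaucoma library, where mitochondrial UMIs, also a sign of RNA quality, were a larger share. In nuclear-encoded oxidative phosphorylation 2 of 27 were higher, 0 lower and 25 between, with a median of 0.43 [0.38, 0.45], and UQCRH (1.46) and NDUFC2 (1.03) led while SDHB (-0.02) and NDUFB1 (-0.03) were lowest. Of the mitochondrial genome 5 of 10 genes were higher, 0 lower and 5 between, with a median of 0.97 [0.91, 1.08]. MT-CO1 was at 6431 and 1887 CPM (1.77 [1.74, 1.80]) and higher in 5 of 5 clusters, and MT-ATP6 was at 1.39, but at 0.72 with the same cluster weights. MT-ND6 stood at 0.34 and MT-ND2 at 0.41, but MT-ND2 was lower in 5 of 5 clusters. The medians of both lists with the same cluster weights were 0.19 and 0.49. The mitochondrial list was also above 0 in T or NK cell-like (0.56), myelinating Schwann cell-like (0.41), pericyte-like (0.35), vascular endothelium-like (0.32) and muscle-like cells (0.30). The interferon response of trabecular meshwork-like cells was higher, with 4 of 22 higher, 2 lower and 16 between and a median of 0.31 [0.17, 0.42], from IFI27 (2.60) and OAS1 (1.40, but 0.25 with the same cluster weights) down to XAF1 (-1.03) and IRF1 (-1.21). This median was -0.13 [-0.24, 0.04] with the same cluster weights.

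The other lists of trabecular meshwork-like cells were mixed. In hypoxia and glycolysis 7 of 22 were higher, 4 lower and 11 between, with a median of 0.12 [0.01, 0.26] that was -0.02 in thinned cells. The glucose transporter gene SLC2A1 was at 445 and 136 CPM (1.71 [1.61, 1.82]) and P4HA2 at 1.89, whereas SLC2A3 and ADM were both at -2.14. The same cluster weights put SLC2A1 at 0.49, P4HA2 at 0.41, SLC2A3 at -1.15 and ADM at -1.01. Oxidative stress defence had 2 of 22 higher, 4 lower and 16 between (0.06 [-0.06, 0.13], or 0.18 [0.12, 0.30] with the same cluster weights), with GPX4 (1.46) and MT1E (1.02) higher and GPX3 (-2.76, or -1.19 with the same cluster weights) and NQO1 (-2.12) lower. Endoplasmic reticulum stress had 1 of 18 higher, SDF2L1 (1.38), 1 lower, XBP1 (-1.03), and 16 between (-0.16 [-0.21, -0.05]), among them SEL1L (0.33) and DDIT3 (-0.62). Aquaporins and ion transport had 1 of 15 higher, 3 lower and 11 between (-0.31 [-0.38, -0.23]). The potassium channel gene KCNJ2 (-2.69) was lower, SLC4A4 (0.80) between and KCNAB1 higher (2.53), but the last 2 stood at -0.23 and -0.25 with the same cluster weights, and SLC4A4 was lower in 4 of 5 clusters. Senescence had 2 of 12 higher, 3 lower and 7 between (0.01 [-0.21, 0.09]), with the cell cycle inhibitor gene CDKN1A at -1.66, IGFBP5 at 337 and 1889 CPM (-2.49 [-2.54, -2.44]; -1.01 with the same cluster weights), IGFBP3 at 1.32 and IGFBP7 at 448 and 106 CPM (2.08 [1.96, 2.20]). Of antigen presentation 4 genes were measured, all between: MAMU-A (-0.16), B2M (0.08), MAMU-E (0.11) and MAMU-DRA (0.14). With the same cluster weights NQO1 stood at -1.36, KCNJ2 at -1.89 and CDKN1A at -1.02. No gene of the damaged-cell and nuclear RNA list had a named feature.

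The highest ratio in trabecular meshwork-like cells was that of TNNT1, slow skeletal troponin T, with 1957 UMIs in the glaucoma library (175 CPM) and 3 in the normal library (0.470 CPM), a log2 ratio of 8.54 [6.99, 10.82]. SMPX, a small muscle protein gene, was at 5.31 [4.67, 6.05], the cholinesterase gene BCHE at 4.39 and IL13RA2 at 4.36. Also among the 12 highest were MYH1 (3.43), KRT7 (3.28), SCG5 (3.25), PGM2L1 (3.16), CAVIN2 (3.14), CAV3, the muscle caveolin (3.12), and EPHA7 (3.11). With the same cluster weights 7 of these 11 named genes stayed at least 2-fold higher, and SCG5 (0.20), CAVIN2 (0.27), EPHA7 (0.74) and PGM2L1 (0.90) did not. Most of the 7 were smaller there too, with SMPX at 2.23, IL13RA2 at 2.82, MYH1 at 2.31, BCHE at 1.31, KRT7 at 1.37 and CAV3 at 1.37, while TNNT1 stood at 8.66. The lowest was LIX1, with 1 UMI in the glaucoma library and 124 in the normal library (-7.76 [-13.08, -5.26]). CCDC152 (-4.33), CNMD, or chondromodulin, a cartilage protein gene (-4.30), CBLN2 and EDIL3 (both -3.27), PLA1A (-3.13), SYBU (-3.09), NR4A3 (-3.02), FGF18 (-2.96), PKHD1L1 (-2.88), SLITRK2 (-2.87) and CXCL2 (-2.84) followed. Of these 12, 10 stayed at least 2-fold lower with the same cluster weights, with PLA1A (-0.90) and FGF18 (-0.75) as exceptions. All 12 were smaller there, among them LIX1 at -5.11, CCDC152 at -3.78, EDIL3 at -2.07, NR4A3 at -1.93, CBLN2 at -1.89, CNMD at -1.66 and SYBU at -1.49. In cluster 23 alone PKHD1L1 stood at 1.25 and PGM2L1 at -2.34.

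In muscle-like cells, the matrix and Wnt lists were higher in the glaucoma library over the whole class, but the matrix list less so within single clusters. The markers do not show which of these cells are ciliary muscle. Cluster 9 had 6 pericyte markers, with RERGL and COX4I2 among its leading genes as in pericyte-like cluster 5. It made up 4.33% of kept glaucoma and 7.48% of normal cells. Cluster 15, led by MYH11 and CHRM3, made up 3.14% and 11.8%. The matrix list had 9 of 21 members higher, 0 lower and 12 between, with a median of 0.82 [0.59, 1.08], and the Wnt list 5 of 9 higher, 0 lower and 4 between, with a median of 1.18 [0.77, 1.54]. Endothelin and contractile receptors (-0.53 [-0.71, -0.31], 0 of 11 higher and 1 lower, but 0.01 with no UMI minimum) and nitric oxide and cyclic nucleotide relaxation (-0.39 [-0.58, -0.29]) lay below 0. Contractile filaments had a median of 0.19 [-0.02, 0.22] in this class, with ACTA2 at 8182 and 7084 CPM (0.21), TAGLN at 8728 and 6440 CPM (0.44), MYL9 at -0.34 and MYLK at -0.68. Among the genes with the largest ratios, CXCL14 (4.15), ITGBL1 (3.91) and TSPAN13 (3.74) were higher, and SMPD3 (-4.33), TRABD2A (-4.12), KCNJ16 (-2.66) and DSP (-2.62) lower. CXCL14 was also a leading gene of trabecular meshwork-like clusters 2, 3, 6 and 20, and ITGBL1 of unnamed cluster 13. Whether RNA of such cells adds to these ratios was not tested. IGKC, an immunoglobulin gene, was at 8.55 because 1 barcode held 97.7% of its UMIs in the glaucoma library, and at 3.13 without that barcode. Cluster 9 held 51.7% of the class in the glaucoma library and 38.2% in the normal library, cluster 15 held 37.5% and 59.9%, and cluster 17 held 10.7% and 1.89%. Cluster 17 also carried MYOC at 13698 and 24524 CPM, and without it the matrix median was 0.51 [0.44, 0.80] and the filament median -0.05 [-0.13, 0.28]. The matrix median was 0.08 [-0.03, 0.27] in cluster 9 alone and 0.30 [0.16, 0.45] in cluster 15 alone. The Wnt list had fewer than 5 measured members without cluster 17, so its median cannot be given without that cluster, and it was 0.28 over every deposited barcode. CXCL14 stood at -0.14 in cluster 9 alone. The median of TGF-beta and BMP signalling, 0.19 [0.04, 0.39], was below 0 without cluster 17, in cluster 9 or 15 alone, in thinned cells and over every barcode.

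In stromal fibroblast-like cells immediate early genes were lower (median -1.16 [-1.29, -1.02], 1 of 18 higher and 10 lower) and oxidative stress defence was higher (0.45 [0.34, 0.50]). The cluster mix of this class differed too, with 485 glaucoma and 341 normal cells in cluster 0, 413 and 686 in cluster 7, 389 and 495 in cluster 12, and 3 and 68 in cluster 24, and its values were not set to equal cluster weights. The named genes were CPZ (2.61), LRRC24 (2.17), GPHA2 (2.11) and IGKC (2.08) above, and SCGB3A1 (-6.53), CXCL2 (-3.48), NR4A3 (-3.08) and CCDC152 (-2.96) below. SCGB3A1, a secretoglobin, was above 0 when the cells or clusters were chosen in another way, from 0.36 over every deposited barcode to 0.91 with doublets kept. ACTA2 was at 145 and 70.6 CPM (1.04 [0.85, 1.24]). In pericyte-like cells MYLK was at 706 and 1343 CPM (-0.93 [-1.08, -0.78]). There CXCL14 (2.45, or 3.04 without 1 normal barcode), CCL26 (1.83), TNNT1 (1.79) and IFI27 (1.75) were higher and NFKBIZ (-2.41), MYLIP (-1.98), CPXM2 (-1.94) and CCDC88A (-1.91) lower. TNNT1 (8.54) and IFI27 (2.60) were higher in trabecular meshwork-like cells as well, and free RNA was not tested for these genes. In vascular endothelium-like cells MT1JP (3.49), APOE (2.81), CRYAB and RAMP1 (both 2.55) were higher, and HS3ST1 (-1.71), GJA5, a gap junction gene of arteries (-1.67), IGFBP5 (-1.66, or -1.04 without 1 normal barcode that held 35.4% of its UMIs) and PCSK5 (-1.55) lower. GJA5 was a leading gene of cluster 18, which held 59 glaucoma and 52 normal cells of this class, beside 583 and 257 in cluster 14.

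Macrophage-like cells had HES6 (3.32), CRYAB (2.81), PPIA (2.31) and RAMP1 (2.22) higher. They had KLF10 (-2.44), ABCA1, a cholesterol exporter (-2.12), and MERTK, a receptor for the uptake of dead cells (-2.10), lower. Their inflammation list had 0 of 12 members higher and 5 lower, with a median of -0.65 [-0.89, -0.50], but of 0.04 in thinned cells. T or NK cell-like cells had STIMATE (3.16), CALD1 (2.89), TPM2 (2.76) and CST3 (2.53) higher, and ZFP36L1 (-1.66), KLF6 (-1.57), IFNG, the gene of interferon gamma (-1.49), and TRIM22 (-1.38) lower. CST3 stood at 709 and 123 CPM there, against 7542 and 4621 CPM in trabecular meshwork-like cells, and TPM2 at 711 and 105 CPM, against 8558 and 6957 CPM in muscle-like cells. CRYAB was also called higher in trabecular meshwork-like cells (1.29) and was a leading gene of their cluster 2. STIMATE was a leading gene of muscle-like cluster 9. Whether free RNA adds to the ratios of these genes was not tested. Myelinating Schwann cell-like cells had IL17B (2.56), MGLL (1.96), POU3F1 (1.95) and TIMP2 (1.83) higher, and CCL26 (-4.05), PRELP (-3.24), IGFBP6 (-3.06, or -2.34 without 1 normal barcode that held 40.4% of its UMIs) and NFKBIZ (-3.04) lower. Non-myelinating Schwann cell-like cells had FCGRT (2.89), STIMATE (2.36), YJEFN3 and PCSK1N (both 1.86) higher, and IBSP (-3.13), RBBP6 (-2.05), C1QL1 (-1.98) and CRTAC1 (-1.84) lower.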

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

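The comparisons in this part were made only after the clusters had been seen. The naming rule left clusters 13 and 21 without a class, and both were larger in the glaucoma library than the limit set by the normal library. Cluster 13 made up 7.26% of kept glaucoma cells (605 cells) and 1.62% of normal cells (87 cells), a share above the upper bound of 1.99% in the normal library. It held 9 trabecular meshwork markers and 9 stromal fibroblast markers, with BMP3, MGARP and WIF1 as its first leading genes and COL8A2, a corneal endothelium marker, among them. BMP3, MGARP, WIF1 and SLC4A10 were also leading genes of trabecular meshwork-like cluster 3. Naming by the number of markers alone put cluster 13 in the trabecular meshwork-like class, which then held 2445 glaucoma and 938 normal cells. Cluster 21 made up 0.348% of glaucoma cells (29 cells) and 0 of 5385 normal cells, with an upper bound of 0.0685% in the normal library. Its first leading genes were TAC1, CRHBP and PTN. As both clusters lie mostly or wholly in 1 library, they can mark that library rather than a cell type, and no explanation was tested for either.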

How the results depend on the processing

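The tests in this part that were chosen after the data had been seen are those on single clusters, the same cluster weights, the naming by markers alone, the class without cluster 17 and the sums without 1 barcode. Under the 5 alternatives fixed in advance the log2 ratio of the share stayed between 3.35 and 3.53 for lymphatic-type endothelium-like, 1.27 and 1.47 for macrophage-like and 1.43 and 2.38 for melanocyte-like cells, and between 0.88 and 1.02 for T or NK cell-like cells under the 4 that gave a value. Of the named genes in trabecular meshwork-like cells, 122 of 136 kept their sign under every one of the 10 alternatives fixed in advance that gave the gene a value. In the other classes 12 of 12 did in T or NK cell-like (under 9 alternatives, as the stricter filter left no such class to compare), 9 of 14 in macrophage-like, 12 of 17 in muscle-like, 10 of 14 in myelinating and 14 of 14 in non-myelinating Schwann cell-like, 13 of 16 in pericyte-like, 12 of 16 in stromal fibroblast-like and 11 of 16 in vascular endothelium-like cells. No UMI minimum cannot change the ratio of a gene, so for genes it is no check. TMM scaling and the leaving out of mitochondrial, ribosomal protein and haemoglobin genes shift all ratios of a class alike. In trabecular meshwork-like cells these shifts were 0.040 and 0.037. Over all alternatives, fixed in advance or added, 1003 values of genes moved beyond their counting interval, 39 reversed and 2559 did neither. The 2559 include 255 values with no UMI minimum, which could not move. For lists the numbers were 394, 41 and 1436, and for shares 15, 1 and 60. The values below are log2 ratios (for lists, medians). The cause was not tested, except where the alternative gives it by its construction. TMM scaling adds 0.20 to every ratio of macrophage-like and of vascular endothelium-like cells and 0.12 in stromal fibroblast-like cells. Depth limits the thinned cells, which leave out 477 glaucoma and 158 normal non-myelinating Schwann cell-like cells.

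Shares. Over every deposited barcode muscle-like cells were at -0.53, stromal fibroblast-like at -0.53 and trabecular meshwork-like at 0.66. With the stricter filter muscle-like cells were at -1.499, myelinating Schwann at -1.69, non-myelinating Schwann at -1.47, pericyte at -1.49, stromal fibroblast at -0.57, trabecular meshwork at 0.71 and vascular endothelium at 0.89. The share of trabecular meshwork-like cells was at -0.11 with doublets kept, 0.84 clustered separately, 0.16 after integration and 0.75 with naming by markers alone. That of stromal fibroblast-like cells was at -1.11 clustered separately and -0.76 after integration.

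Trabecular meshwork-like cells, alternatives fixed in advance. Contractile filaments (0.39) were at 0.35 with the stricter filter, 0.16 with doublets kept, 0.15 after integration and 0.44 with the same weight for every cell. PPP1R1B (3.56) was at -0.54 after integration. The relaxation list (-0.03) was at 0.10 clustered separately. With no UMI minimum calcium handling (-0.31) was at -0.087 and hypoxia (0.12) at -0.041. In thinned cells endothelin and contractile receptors (-0.18) were at 0.12 and hypoxia at -0.020.

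Trabecular meshwork-like cells, alternatives added. In cluster 2 alone PTGER2 was at -0.47, PLCB4 at -0.36, EDNRA at -0.29, PPP1R1B at -1.09, KCNAB1 at -0.16, contractile filaments at 0.15 and the relaxation list at -0.497. In cluster 20 alone CAVIN2 was at -0.29, CAV3 at -0.15, EPHA7 at -1.32, PTGER2 at -0.37, PLCB4 at -0.71, ITGA2 at 0.45, the relaxation list at -0.34, endothelin and contractile receptors at -0.33, endoplasmic reticulum stress at 0.057, the interferon response at -0.11 and hypoxia at -0.090. In cluster 23 alone MYH1 was at -0.34, PGM2L1 at -2.34, PKHD1L1 at 1.25, PTGER2 at -0.34, S1PR3 at 0.66, PLCB4 at -0.25, EDNRA at -0.60, ANGPT1 at 0.34, CHAD at 0.77, CRYAB at -0.14, IL11 at -0.75 and ADM at 0.088. There contractile filaments were at 0.064, calcium handling at 0.036, fibrillar and basement membrane matrix at -0.028, inherited glaucoma and outflow loci at 0.26 and nuclear-encoded oxidative phosphorylation at -0.0066. With the same cluster weights PTGER2 was at -0.13, PLCB4 at -0.40, EDNRA at -0.49, ITGA2 at 0.16, PPP1R1B at -0.059, KCNAB1 at -0.25, contractile filaments at 0.22, the relaxation list at -0.42, endothelin and contractile receptors at -0.36 and the interferon response at -0.13; since only the weights differ there, the mix of clusters moved these values.

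Other classes. In stromal fibroblast-like cells SCGB3A1 (-6.53) was at 0.36 over every barcode, 0.41 with the stricter filter, 0.91 with doublets kept, 0.78 clustered separately and 0.69 after integration. There the stricter filter put TGF-beta and BMP signalling (-0.17) at 0.0100 and endoplasmic reticulum stress (0.16) at -0.050, and thinning put hypoxia (0.28) at -0.10 and senescence (-0.23) at 0.42. MYOC in myelinating Schwann cell-like cells (-1.28) was at 0.68 over every barcode, 0.48 with doublets kept and 2.04 after integration. In muscle-like cells TGF-beta and BMP signalling (0.19) was at -0.33 over every barcode, -0.17 in thinned cells, -0.27 in cluster 9 alone, -0.19 in cluster 15 alone and -0.032 without cluster 17. Nuclear-encoded oxidative phosphorylation (-0.12) was at 0.16 over every barcode, 0.23 in cluster 9 alone and 0.051 in cluster 15 alone. Matrix turnover there (0.31) was at -0.071 in thinned cells and -0.36 in cluster 9 alone, CXCL14 (4.15) at -0.14 in cluster 9 alone, and endothelin and contractile receptors (-0.53) at 0.013 with no UMI minimum. In macrophage-like cells TMM scaling put calcium handling (-0.19) at 0.010, thinning put inflammation (-0.65) at 0.041, and separate clustering put contractile filaments (0.54) at -0.26. In vascular endothelium-like cells matrix turnover (-0.18) was at 0.065 over every barcode, 0.051 with doublets kept and 0.020 with TMM scaling. TMM scaling there put integrins (-0.16) at 0.039, endoplasmic reticulum stress (-0.12) at 0.078 and inflammation (-0.17) at 0.034, and no UMI minimum put inflammation at 0.13. With no UMI minimum heat shock in T or NK cell-like cells (-0.27) was at 0.17, inflammation in pericyte-like cells (0.60) at -0.069, and in non-myelinating Schwann cell-like cells the relaxation list (-0.44) at 0.046 and integrins (-0.23) at 0.045. In pericyte-like cells TGF-beta and BMP signalling (-0.66) was at 0.087 with doublets kept.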

Other observations

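All tests of explanations in this part were chosen after the results they bear on had been seen. Some gene lists leaned the same way in many classes. Oxidative stress defence, with antioxidant enzymes and metal-binding proteins, was above 0 in pericyte-like cells (median 0.63 [0.40, 0.74]), non-myelinating Schwann cell-like cells (0.56 [0.32, 0.67]), myelinating Schwann cell-like cells (0.46 [0.40, 0.69]), muscle-like cells (0.39 [0.24, 0.49]) and vascular endothelium-like cells (0.24 [0.11, 0.57]). Nuclear-encoded oxidative phosphorylation was above 0 in those classes too, from 0.21 [0.14, 0.32] in vascular endothelium-like to 0.37 [0.26, 0.46] in myelinating Schwann cell-like cells, but at -0.12 [-0.14, -0.08] in muscle-like cells, where the sign turned over every deposited barcode (0.16) and in clusters 9 (0.23) and 15 (0.051) alone. In trabecular meshwork-like cells oxidative stress defence was at 0.18 [0.12, 0.30] with the same cluster weights. Inherited glaucoma and outflow loci were lowest in stromal fibroblast-like cells (-0.54 [-0.69, -0.34]), where 1 of 19 genes was called higher and 4 lower. TGF-beta and BMP signalling was at -0.66 [-0.84, -0.21] in pericyte-like cells (but at 0.087 with doublets kept) and -0.44 [-0.53, -0.25] in vascular endothelium-like cells. Antigen presentation was at 0.32 [0.06, 0.42] in vascular endothelium-like cells and at -0.00147 in macrophage-like cells.

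Of the sex-linked genes, DDX3Y, UTY, KDM5D, USP9Y, ZFY, RPS4Y1 and RPS4Y2 had 0 UMIs in both libraries, which allows up to 0.0774 CPM in the glaucoma library and 0.1198 CPM in the normal library. EIF1AY had 2 and 3 UMIs and NLGN4Y 1 and 3. XIST was not analysed here, and the sex of the animals is not given in the labels.

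The higher contractile filament genes of trabecular meshwork-like cells in the glaucoma library were set against free RNA and against the mix of clusters. If free RNA adds like numbers of UMIs to every droplet, it does not account for TAGLN, ACTA2 and CNN1. Their excess per cell was at least 2.97 times the highest level in immune and Schwann cell-like cells of that library. It may account for DES, at 0.651 times that level. The measure leaves depth aside, with medians of 5494 UMIs in trabecular meshwork-like and 1353.5 in T or NK cell-like cells of that library. Free RNA that rises with depth was not tested, nor were uncalled doublets with contractile cells. ACTB was set apart from the others after its value of 0.199 was seen. That measure cannot decide on it, because macrophage-like cells hold more of it (16.0 UMIs per cell) than trabecular meshwork-like cells (6.25). The excess of ACTB, 3.18 [3.03, 3.34] UMIs per cell, was above the level in non-myelinating (1.71) and myelinating (2.26) Schwann cell-like cells. It was below the level in T or NK cell-like cells (4.86), and ACTB stays undecided. A different mix of clusters is not the whole source of the list's median, which was 0.22 [0.14, 0.29] with the same cluster weights against 0.39 without. These weights rest on only 17 normal cells in cluster 3. In single clusters the median was 0.15 [0.04, 0.28] in cluster 2, 0.37 [0.29, 0.46] in cluster 20 and 0.06 [-0.14, 0.14] in cluster 23. A difference tied to the diagnosis stays open and untested, as do the animal, the dissection and the day of preparation.

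The lower immediate early genes were weighed in the same way. With the same cluster weights the median was -0.75 [-0.87, -0.50] in trabecular meshwork-like cells, so the mix of clusters is not its whole source. In single clusters it was -0.83 in cluster 2 and -0.63 in cluster 20, but only -0.15 [-0.34, -0.04] at percentile 23.3 in cluster 23, which held a like share of the class in both libraries. Over whole classes the median was below 0 in 9 of 9 classes, from -1.26 to -0.11, with an interval below 0 in 8, as a difference of the whole library such as the handling of the tissue would give. These genes are known to respond to enzymatic dissociation. The labels give both libraries the same written digestion protocol, which does not show that the digestion or the time before it was equal in practice. Handling therefore stays a candidate explanation. An effect of the disease on every class at once was not tested.

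The larger share of lymphatic-type endothelium-like cells was set against 3 technical explanations. The filter on cells is not its source, as the log2 ratio was 3.35 over every deposited barcode. A like gain of all classes outside the meshwork, fibroblast and muscle classes is excluded, since vascular endothelium-like cells were at 0.42 [0.23, 0.62] against 3.43 [2.92, 3.98]. Another piece of the limbus in 1 dissection cannot be told apart from the diagnosis, as 1 dissection per group leaves this open. Melanocyte-like cells, which may come from outside the meshwork, were at 1.86 [1.08, 2.73]. A larger canal or lymphatic compartment in glaucoma remains a hypothesis without a test here.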
